A study of Mus musculus with 8 samples.

How the data were processed

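Polyadenylated RNA from mouse brain microglia was measured in 8 libraries, 4 WT and 4 Cop1 KO. Per the labels' protocols, total RNA was extracted on columns with DNase digestion, libraries were made with the TruSeq RNA kit v2, and single-end reads were produced on a HiSeq 4000. Per the submitters' processing notes, reads were aligned with GSNAP to GRCm38. The GSNAP version, the gene models and the counting tool are not given in the sources used here. Per the file headers, the count column deposited by the authors holds the number of reads that align uniquely to each gene model, with no normalization. The second column holds RPKM values that the authors adjusted by size factors, per the file headers, and how those factors were made is not given in the sources used here. The files are indexed by NCBI Gene ID, with 36528 IDs in the same order in each. Counting unique reads lowers the count of genes with near-identical copies, such as those with processed pseudogenes. The kit keeps no strand information, so reads of overlapping antisense genes cannot be told apart.

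Groups were taken from the genotype labels. Replicate numbers follow accession order and pair no samples. Design, gene lists, named-gene rule and alternatives were fixed before the data were examined. Gene symbols and coordinates came from RefSeq genes of GRCm38.p6, matched by Gene ID; 31049 IDs (85.0%) matched, and 931 of the 15253 tested genes did not and were kept under their ID. IDs without a match held 0.98% to 1.42% of the reads of a library. Of 15332 genes with a total of at least 80 reads, 48 had the same counts as another gene in all 8 libraries. No pair of libraries was a repeat of the other, since chi-square per degree of freedom over genes was 20.3 to 77.5 and Spearman's rho over genes 0.965 to 0.989 for the 12 pairs within a group.

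Totals per library were 16460728 to 31306309 reads in Cop1 KO and 25270754 to 34734859 in WT. Counts were tested with edgeR 4.0.16 in R 4.3.3, after filterByExpr and TMM scaling, with a robust quasi-likelihood fit of group alone, a two-sided F-test and Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change is its size divided by the square root of F. Log2 CPM values used a prior count of 2. The common dispersion was 0.071. The procedure was tested on simulated counts for this comparison, with 14950 genes and 200 changed; it recovered 16.4% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 90.9% of those changed 4-fold, with 7 false calls. Most 1.5-fold changes were therefore missed in the simulation. In the data 2398 genes were called, against 200 changed in the simulation. The adjusted threshold then falls at a larger p, so the share missed may be smaller. For Cop1 an exact permutation test of log2 CPM was run as well. For named genes with at most 4 reads in each library of a group, the ratio of depth-scaled counts is given with an exact 95% interval.

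The genes named were Cop1; the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups, leaving out unnamed models, Xist and 4 Y-linked genes, and receptor segments; the 5 others with the smallest p; up to 4 called members of each list with the smallest p, or the 2 most abundant where none was called; and Cebpb, Cebpa, Jun and Etv5. Of the called genes, 1798 met the rule for largest changes apart from rank, and 113 genes were named. Other list members in the text were chosen after their values were seen, to show members that did and did not pass.

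The 32 lists were COP1 ligase and adaptors, COP1 substrate factors, acute-phase genes, cytokines and chemokines, NF-kB feedback, oxidant production, complement, homeostatic microglia, disease-associated microglia, type I interferon response, antigen presentation, alternative activation, cell cycle, ERK output, lysosome, sterol synthesis, lipid efflux and storage, glycolysis and hypoxia, TGF-beta signalling, unfolded protein and ATF4 responses, immediate-early and heat-shock genes, markers of neurons, astrocytes, oligodendrocytes, vascular cells, border macrophages, monocytes, neutrophils, lymphocytes and red blood cells, mitochondrially encoded transcripts, and sex-linked genes. The 30 lists with at least 4 measured members were tested with camera in limma 3.58.1 on voom values, with a correlation preset at 0.01 and adjustment over the 30 lists. By that test 18 lists were called. With an estimated correlation camera called 0, with 4 lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.101, and fry called 19, of which 16 were also among the 18.

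Alternatives were DESeq2 size factors, upper-quartile scaling, library size only, no filter, at least 1 CPM in 4 libraries, the DESeq2 1.42.0 Wald test, limma-voom with and without sample quality weights, limma-trend on log2 of the deposited RPKM plus 1, glmTreat at 1.5-fold, fry, camera with an estimated correlation, and each library left out in turn. Leaving out WT replicate 2 and Cop1 KO replicate 2 together was added after the data were examined, because of their marker levels. Gene families were tested after the data were examined, by Fisher's exact test. Figures were drawn with matplotlib 3.10.9. Raw reads, splicing, exon-level counts and protein were not analysed here. Some members of the gene lists are not reported here.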

Results

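RNA was measured in microglia, the resident macrophages of the brain, taken from mouse brain. The 8 samples form 2 groups, 4 from wild-type microglia (WT) and 4 from microglia in which Cop1 had been deleted in vivo (Cop1 KO). COP1 is a ubiquitin ligase that marks several transcription factors for degradation. The single comparison that the labels give asks how the loss of Cop1 changed the microglial transcriptome. Each sample is one library of polyadenylated RNA, and replicate numbers are names only. The WT libraries held 34734859, 32811107, 30768292 and 25270754 uniquely aligned gene reads, and the Cop1 KO libraries held 16460728, 27050099, 31306309 and 27302488. The labels do not say whether the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Levels are given as CPM, counts scaled to library size by TMM, with mean ± SD and n = 4 per group. Changes are log2 fold changes of Cop1 KO against WT with their SE, and tests are two-sided.

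Cop1 itself (Gene ID 26374, chromosome 1, 159232156 to 159354872 in GRCm38) was lower in each Cop1 KO library than in each WT library. It measured 6.09 ± 0.245 CPM (SD, n = 4) in WT and 4.45 ± 0.588 CPM in Cop1 KO. The WT libraries held 220, 188, 178 and 160 Cop1 reads and the Cop1 KO libraries 65, 142, 143 and 113. An exact two-sided permutation test of the log2 CPM gave p = 0.0286, the smallest that the 70 assignments of 4 and 4 samples allow. In the edgeR quasi-likelihood fit the log2 change was -0.45 (SE 0.19; edgeR adjusted p = 0.137), so it did not pass the threshold. Reads were counted over the whole gene. Which exons were removed is not given in the sources used here, and reads from exons that remained would still count, so the level does not measure how complete the deletion was.

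Of 15253 tested genes, 2398 (15.7%) passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, 1283 higher and 1115 lower in Cop1 KO. Of these, 610 were more than 2-fold higher and 369 more than 2-fold lower. The first principal component held 39.5% of the variance and separated the groups, with the WT libraries at -60.4 to -36.0 and the Cop1 KO libraries at 38.3 to 54.6. The second held 21.7% and set Cop1 KO replicate 2 apart at 63.9. The 4 values of one group lay wholly above those of the other for 3266 tested genes (21.4%), where chance gives 2.9%.

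The largest rise was that of Cxcr2 (Gene ID 12765, chromosome 1, 74153994 to 74161246), the receptor for neutrophil-attracting chemokines. It rose from 0.0775 ± 0.0559 to 59.1 ± 10.1 CPM (SD, n = 4), with 10 reads in the WT libraries together and 6106 in the Cop1 KO libraries. Scaled to depth this is a ratio of 735, with a counting interval of 399.5 to 1534. Saa3 (Gene ID 20210, chromosome 7, 46711998 to 46719615), an acute-phase apolipoprotein, had 3 reads in WT and 1148 in Cop1 KO, a ratio of 461 (157 to 2237). These intervals cover counting error only. Il12b, the shared subunit of interleukins 12 and 23, rose by 5.99 (SE 0.72) on the log2 scale, from 0.0987 ± 0.155 to 7.17 ± 2.99 CPM. Ifitm1, a restriction factor against viruses, rose by 5.37 (SE 0.43), and Acod1, the enzyme that makes itaconate, by 5.11 (SE 0.59). Their WT means were 0.328 and 0.220 CPM. Siglec1, a sialic acid receptor of activated macrophages, reached 218 ± 33.1 CPM from 6.46 ± 3.05. Cped1, Adam8, Ctse and Ptpru rose by 4.72, 4.52, 4.46 and 4.38, from WT means of 0.228, 1.99, 1.67 and 0.363 CPM. Where the WT level is near 0, the size of a log2 change is uncertain. Among the genes with the smallest p, Tnfsf13b, which encodes the B-cell survival factor BAFF, rose from 22.4 ± 2.84 to 167 ± 11.5 CPM, and Igsf6 rose 4.11-fold.

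The largest fall was that of Gpr165 (Gene ID 76206, chromosome X, 96713468 to 96719388), an orphan receptor, from 111 ± 21.9 to 3.04 ± 0.933 CPM (SD, n = 4), a log2 change of -5.17 (SE 0.23). Sema4b, a semaphorin, followed at -4.66 (SE 0.52), then Tmem44 at -3.95 (SE 0.23). Gp9, known as a platelet glycoprotein, was at -3.91 (SE 0.14), with 47.4 ± 1.51 CPM in WT and 3.14 ± 0.444 in Cop1 KO. Myo18b, Fcrls, Duoxa1, Vstm4, Mycl and Csmd3 completed the 10 largest falls, at log2 changes from -3.61 to -3.11.

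Every one of the 34 measured genes of the type I interferon response list rose in Cop1 KO microglia, by 0.58 to 4.11 on the log2 scale with a median of 2.52, both over all tested genes and adjusted over the list alone. Ifi204 (chromosome 1, 173747293 to 173767069) rose from 10.1 ± 2.83 to 174 ± 21.3 CPM (SD, n = 4; edgeR adjusted p = 2.37e-07). Irf7 (chromosome 7, 141263183 to 141266499), the transcription factor that amplifies type I interferon production, rose 7.90-fold (edgeR adjusted p = 3.39e-07). Usp18, a feedback inhibitor of interferon receptor signalling, rose 6.53-fold. Ifi209, a neighbour of Ifi204 outside the list, rose 8.24-fold. As a set the list moved against all other genes in limma's camera test with a preset correlation (adjusted p = 4.84e-40). With an estimated correlation the camera adjusted p = 0.101. With fry, which asks only whether a list's genes move on balance one way, the adjusted p = 7.08e-05. The 34 genes also rose when WT replicate 2 and Cop1 KO replicate 2, the libraries that stood apart in marker levels, were left out together.

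Genes of antigen presentation changed in both directions, with 13 of 21 higher and 3 lower, the same counts as adjusted over the list alone. The MHC class I genes H2-K1 and H2-D1 rose 3.14-fold and 3.46-fold, H2-T23, a non-classical class I gene, 2.24-fold, and Nlrc5, the transactivator of class I genes, 5.41-fold. B2m, their light chain, rose from a mean of 1939 to 4057 CPM. The class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 did not pass the threshold, with log2 changes of 0.13, 0.23, 0.19 and 0.37. Of the class II peptide-loading genes, H2-DMa rose by 1.21 and H2-DMb1 fell by 0.63. The costimulatory genes split, since Cd40 rose by 2.00 (SE 0.47) while Cd80 and Cd86 fell by 1.12 and 0.47 on the log2 scale. The camera adjusted p = 1.94e-06 for the list, and the adjusted p = 0.221 with an estimated correlation. Class I genes of the H2 complex resemble one another closely, so their unique read counts are uncertain.

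**Figure D1:**
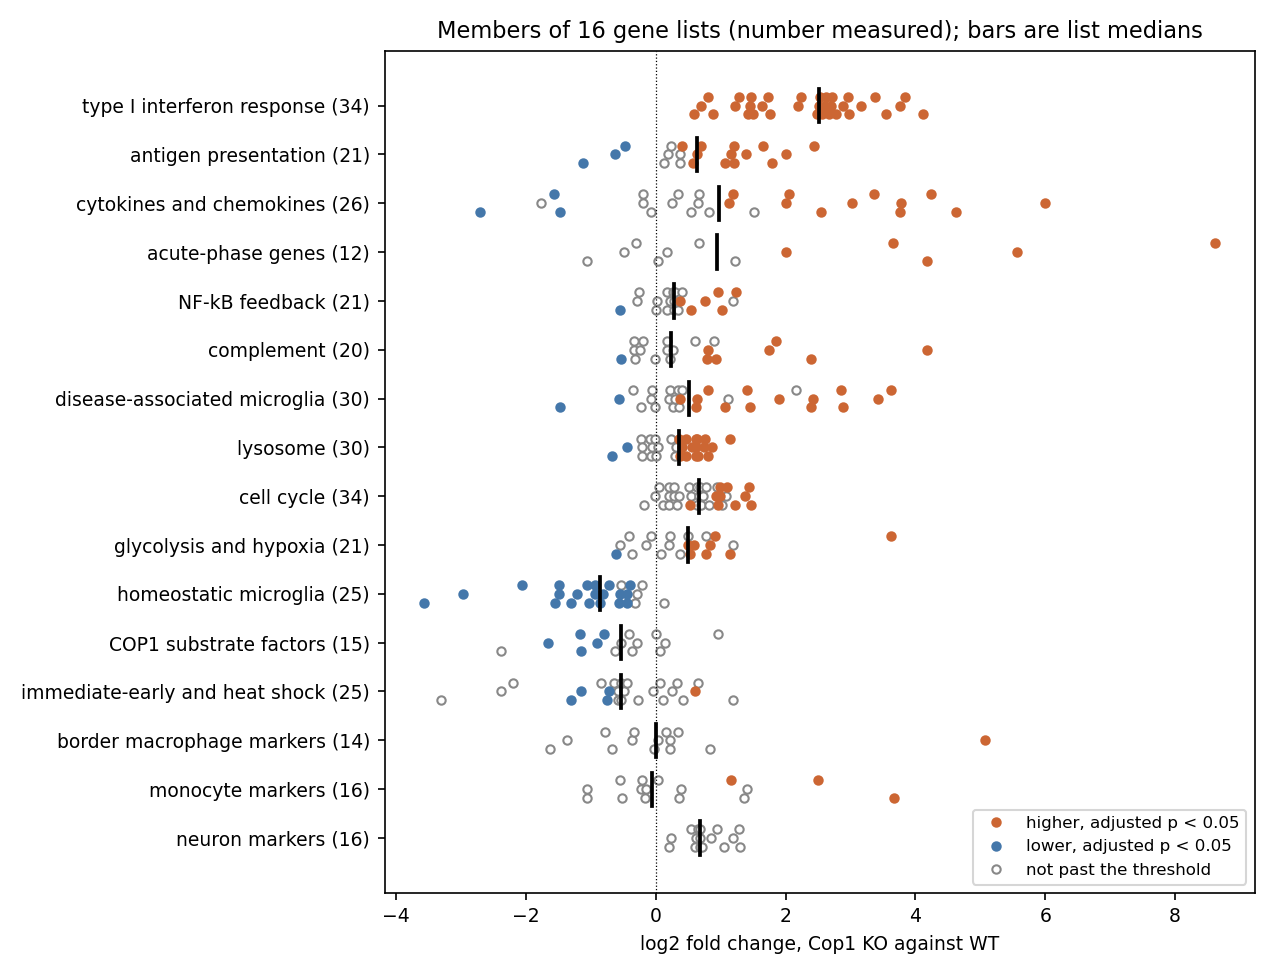
Log2 fold change of each measured member (points) of 16 gene lists, Cop1 KO against WT, with the list median as a bar. Orange and blue points passed the edgeR adjusted p threshold of 0.05 as higher or lower, and open points did not. All 34 interferon genes lay above 0, with a median of 2.52, and 20 of 25 homeostatic genes were past the threshold as lower.

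Of 26 measured inflammatory cytokines and chemokines, 12 rose and 3 fell, or 15 and 3 adjusted over the list alone. Il1rn, the interleukin 1 receptor antagonist, rose from 1.04 ± 0.412 to 19.8 ± 1.84 CPM (SD, n = 4). Cxcl10, an interferon-induced chemokine that the interferon list also holds, rose 13.6-fold, and Ccl12, a ligand of the monocyte receptor CCR2, 5.86-fold. Il1b rose 4.01-fold and Tnf by 1.13 (SE 0.32) on the log2 scale, whereas Il6 (0.66, SE 0.22; edgeR adjusted p = 0.0612) and Il1a (-0.19, SE 0.22) did not pass. The 3 that fell were Ccl9, Ccl24 and Ccl6, with Ccl9 6.55-fold lower. The camera adjusted p = 4.99e-05 for the list, and the adjusted p = 0.221 with an estimated correlation.

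Of 20 listed acute-phase and secreted genes with promoters driven by C/EBP factors, 12 were measured. Of these 5 rose, with none lower, or 6 adjusted over the list alone. Besides Saa3 these were C3, Il1b, Lcn2 and Ptgs2. Saa3, Lcn2 and Ptgs2 had WT means of 0.027, 0.015 and 0.11 CPM. They passed the filter through Cop1 KO and could be called only as higher, so the counts and the set test are partly fixed by the filter. C3, the central complement component, rose from 5.25 ± 3.56 to 94.6 ± 23.9 CPM (SD, n = 4). Lcn2, an iron-trapping lipocalin, had 2 reads in WT and 103 in Cop1 KO, a ratio of 62.0 (16.7 to 519). Hp, Lbp and Cd14 did not pass the threshold, at -1.06, -0.49 and -0.31. The camera adjusted p = 0.00265 for the list, and the adjusted p = 0.221 with an estimated correlation.

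NF-kB feedback genes numbered 6 higher and 1 lower of 21 (8 and 1 adjusted over the list alone), with a median of 0.28. Tlr2, a receptor for bacterial lipopeptides, rose 2.36-fold, Bcl3 2.03-fold and Irf1 1.69-fold, while Nfkb1 fell 1.47-fold. Without WT replicate 4, Cop1 KO replicate 1 or Cop1 KO replicate 4, 3 members rose. For the list as a set, the camera adjusted p = 0.00464, and the adjusted p = 0.221 with an estimated correlation. Of 8 oxidant-producing genes, 1 rose, also when adjusted over the list alone. It was Cybb, the catalytic subunit of the phagocyte NADPH oxidase, which went from 60.7 ± 37.7 to 505 ± 33.8 CPM (SD, n = 4). That list was not called as a set (camera adjusted p = 0.0706), but was called without WT replicate 3 (0.0254) and without Cop1 KO replicate 2 (0.0305), with library size only (0.0435), with no filter (0.0462), with fry (0.0343), and without WT replicate 2 and Cop1 KO replicate 2 together (0.0224).

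The complement list held 7 of 20 genes higher and 1 lower, or 8 and 3 adjusted over the list alone. C3 and the receptor subunits Itgax and Itgb2 rose 18.1-fold, 5.23-fold and 1.90-fold, and the anaphylatoxin receptor C3ar1 rose 1.75-fold. C4b rose by 1.75 on the log2 scale and Cfb from a mean of 2.97 to 10.7 CPM. C1qa, C1qb and C1qc, which microglia make in large amounts, did not pass over all genes, with log2 changes of -0.34, -0.25 and -0.34. Tested as a set, the list gave a camera adjusted p of 0.0191, and the adjusted p = 0.251 with an estimated correlation. The list median of 0.24 was 0.06 without WT replicate 2 and 0.62 without WT replicate 1, and -0.02 with WT replicate 2 and Cop1 KO replicate 2 left out together. It was 0.55 without WT replicate 3, 0.10 without WT replicate 4, and 0.44, 0.11 and 0.40 without Cop1 KO replicates 1, 2 and 3.

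Homeostatic microglia genes fell in 20 of 25 cases, with none higher, or in 22 adjusted over the list alone. The median log2 change was -0.86. Fcrls, a scavenger receptor-like gene, fell from 4798 ± 317 to 405 ± 92.2 CPM (SD, n = 4). P2ry12 (chromosome 3, 59216271 to 59262985), the ADP receptor that directs process movement, fell from 9382 ± 1176 to 2252 ± 442 CPM. Crybb1 fell 7.84-fold and Gpr34 2.82-fold. Cst3, Sparc, Cx3cr1, Sall1 and Tmem119 fell too, at log2 changes from -1.49 to -0.44. Csf1r, Olfml3, Selplg, Rhob and Cd33 did not pass, with Csf1r at -0.29 (SE 0.14). Set against all other genes, the camera adjusted p = 5.65e-19, and the adjusted p = 0.101 with an estimated correlation. Without WT replicate 2 and Cop1 KO replicate 2, 16 of the 25 were called lower.

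**Figure D2:**
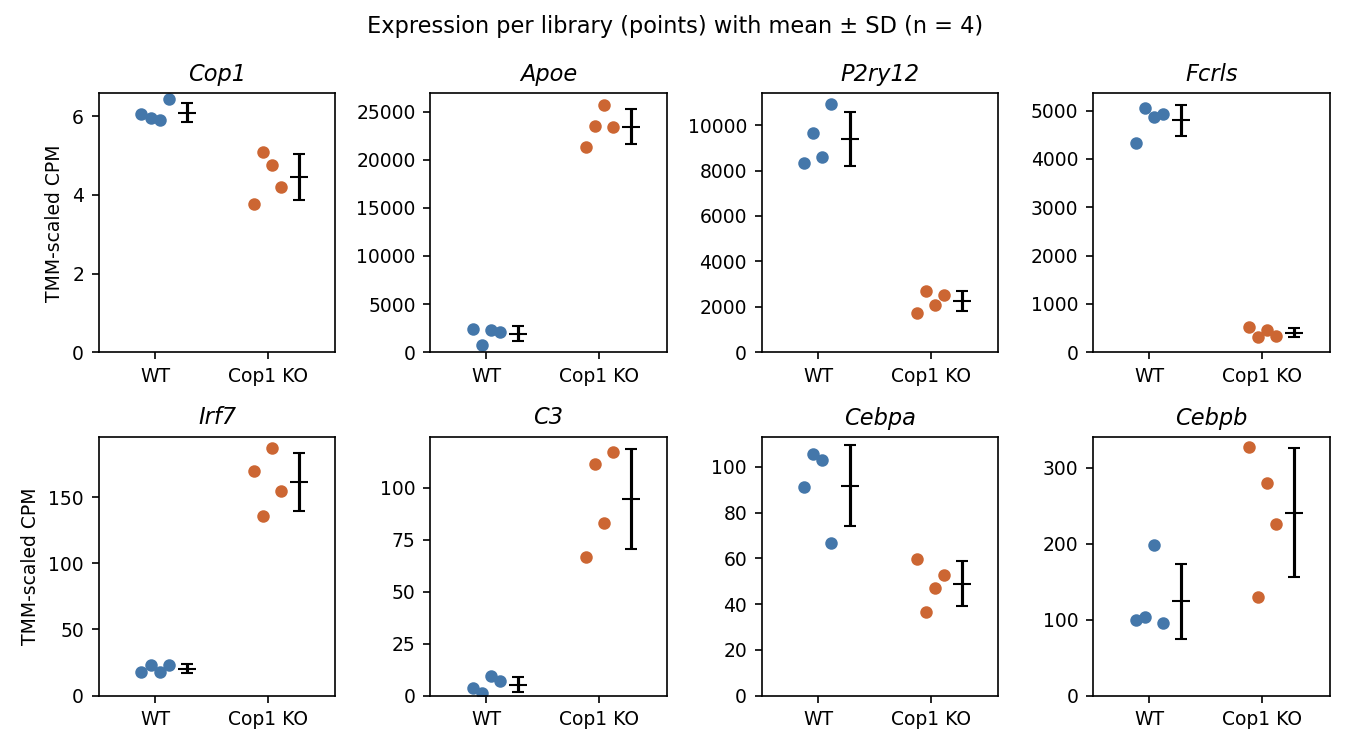
TMM-scaled CPM of 8 genes in each library (points; 4 WT and 4 Cop1 KO), with mean and SD as a black bar. Each y axis starts at 0. The Cop1 KO libraries lay below WT for Cop1, P2ry12, Fcrls and Cebpa and above it for Apoe, Irf7 and C3, and the groups overlapped for Cebpb.

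Disease-associated microglia genes rose in 14 of 30 cases and fell in 2, or 15 and 3 adjusted over the list alone. Apoe (chromosome 7, 19696244 to 19701310), the main apolipoprotein of the brain, rose from 1894 ± 778 to 23433 ± 1781 CPM (SD, n = 4). It made up 2.23% to 2.45% of the reads in the Cop1 KO libraries and 0.07% to 0.25% in WT. Clec7a, a beta-glucan receptor, rose 7.20-fold and Itgax 5.23-fold, and Axl and Cst7 rose by 2.89 and 1.41 on the log2 scale. Trem2 (-0.23), Tyrobp (0.21), Spp1 (0.36) and Lpl (0.41) did not pass. Ccl6 and Timp2 fell. In the set test, the camera adjusted p = 9.65e-07, and the adjusted p = 0.221 with an estimated correlation.

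Lysosomal genes rose in 16 of 30 cases and fell in 2 (18 and 2 adjusted over the list alone), by smaller amounts, with a median of 0.36. Glb1, Gla, Ctsc and Ctsz rose 1.67-fold, 2.21-fold, 1.83-fold and 1.75-fold. Lgmn fell by 0.68 on the log2 scale. Against the other tested genes, the camera adjusted p = 0.000219, and the adjusted p = 0.366 with an estimated correlation. Of 20 genes of lipid efflux and storage, 4 rose and 2 fell, with the same counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.0890), though fry called it (adjusted p = 0.00363). Besides Apoe, Apoc1, Soat1 and Plin2 rose, Apoc1 16.5-fold from 0.338 ± 0.241 CPM. Lpcat3 and Mylip fell 1.72-fold and 2.13-fold, and Abca1 and Abcg1 did not pass, at 0.32 and 0.28. Of 18 genes of sterol synthesis and uptake, 4 rose, also when adjusted over the list alone. Among them Srebf2 was 1.65-fold and Sqle 2.18-fold higher, and Lss 1.71-fold. The Lss call ended without WT replicates 1, 3 or 4 or Cop1 KO replicates 1 or 2. For the sterol list as a set, the camera adjusted p = 0.00728, and the adjusted p = 0.221 with an estimated correlation.

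Proliferation genes rose in 10 of 34 cases with none lower, or in 18 adjusted over the list alone. Mki67 went from 8.80 ± 2.96 to 22.9 ± 6.76 CPM (SD, n = 4), and Bub1b, Top2a and Tpx2 rose 2.34-fold, 2.14-fold and 1.95-fold. These are low levels, and the replication genes Mcm2, Mcm3 and Pcna did not pass, at 0.20, -0.18 and 0.05. Tested as a set, the list gave a camera adjusted p of 4.71e-07, and the adjusted p = 0.282 with an estimated correlation. The number called fell to 6 without WT replicate 2 and to 5 without WT replicate 3, Cop1 KO replicate 1 or Cop1 KO replicate 4.

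Of 21 genes of glycolysis and the hypoxia response, 8 rose and 1 fell, or 11 and 3 adjusted over the list alone. Egln3, a prolyl hydroxylase induced by hypoxia, rose from 0.479 ± 0.165 to a mean of 5.97 CPM in Cop1 KO. Hk2 rose 2.20-fold while Hk1 fell by 0.61 on the log2 scale, and Gpi1 and Eno1 rose by 0.84 and 0.58. Vegfa, Slc2a1 and Pgk1 did not pass, at -0.15, 0.20 and 0.22. Gapdh, which rose by 0.92, was counted at 3.04 CPM in WT. Only uniquely aligned reads were counted, and the gene has many processed copies, so this level may be too low. Set against all other genes, the camera adjusted p = 0.00192, and the adjusted p = 0.221 with an estimated correlation.

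Among transcription factors known as COP1 substrates and their relatives, mRNA levels fell in 5 of 15 cases and rose in none, or fell in 7 and rose in 1 adjusted over the list alone. Cebpa (chromosome 7, 35119293 to 35121928) fell from 91.7 ± 17.7 to 49.0 ± 9.74 CPM (SD, n = 4; edgeR adjusted p = 0.00392). Etv5 fell 3.16-fold, Ets1 2.24-fold and Jund 2.22-fold, and Ets2 fell by 0.80 on the log2 scale. Cebpb (chromosome 2, 167688915 to 167690432) had a log2 change of 0.95 (SE 0.31) and missed the threshold (edgeR adjusted p = 0.0627). It passed without WT replicate 3, at 1.27 (adjusted p = 0.00857), and without Cop1 KO replicate 2, at 1.16 (adjusted p = 0.0106). With all 8 libraries it passed with library size only (0.0478), limma-voom (0.0450) and quality weights (0.0141), and it passed without WT replicate 2 and Cop1 KO replicate 2 together (0.0205). Over all alternatives the adjusted p of Cebpb lay between 0.00857 and 0.182. Jun had a log2 change of -2.39 (SE 0.76; edgeR adjusted p = 0.0750), with 426 ± 525 CPM in WT and 81.3 ± 11.8 in Cop1 KO. Without WT replicate 2 it was -1.02 (adjusted p = 0.00309), and without WT replicate 3 it was -2.70 (adjusted p = 0.0444), past the threshold in both. It also passed in the DESeq2 Wald test (0.0128) and with quality weights (0.0431), and over all alternatives the adjusted p of Jun lay between 0.00101 and 0.194. In the set test, the camera adjusted p = 0.000948, and the adjusted p = 0.221 with an estimated correlation. These are mRNA levels, and protein was not analysed here.

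Of 10 ligase subunits and adaptors of COP1, 2 rose and none fell, also when adjusted over the list alone. Trib1, a scaffold that brings C/EBP factors to COP1, rose 3.08-fold and Cul4b 1.58-fold. Cul4a and Ddb1 did not pass, at -0.11 and 0.05. The list was not called by camera (adjusted p = 0.428) and was called upward by fry (adjusted p = 0.0445), and its median of -0.03 and mean of 0.33 differ in sign. ERK pathway output genes were lower in 2 of 15 cases and higher in 1, or 3 and 1 adjusted over the list alone. Etv5 and Spry1, a feedback inhibitor of the pathway, fell, Spry1 2.27-fold, while Dusp6 did not pass (-0.12, SE 0.13). Phlda1 was the member that rose, from 0.857 ± 0.173 to 2.09 ± 0.649 CPM, and its call ended without WT replicates 1, 3 or 4 or Cop1 KO replicates 2 or 3. The list's camera adjusted p = 0.0441 became 0.0986, 0.0693, 0.0564 and 0.0985 without WT replicates 2 and 4 and Cop1 KO replicates 1 and 3, and the adjusted p = 0.447 with an estimated correlation. It was also lost with upper-quartile scaling (0.0539), at least 1 CPM in 4 libraries (0.0919), quality weights (0.112), the deposited RPKM (0.0795) and fry (0.0768). Without WT replicate 3, 4 members fell.

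Of 17 TGF-beta signalling genes, 1 rose and 2 fell, with the same counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.274). Pmepa1 and Tgfbr1 fell 2.47-fold and 1.82-fold and the corepressor Tgif1 rose 1.64-fold. Of 20 genes of the unfolded protein and ATF4 responses, 1 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.940). Psat1 and Phgdh, which catalyse successive steps of serine synthesis, moved apart. Psat1 rose from 28.2 ± 3.33 to 126 ± 15.1 CPM (SD, n = 4), and Phgdh fell 1.61-fold from 25.8 ± 1.78 CPM. The Phgdh call ended without WT replicate 3 (edgeR adjusted p = 0.0507) and without Cop1 KO replicate 4 (0.0556), and that of Dnajb9, which also fell, without WT replicate 4 (0.0563), Cop1 KO replicate 1 (0.0585) or Cop1 KO replicate 4 (0.0587). The range for Phgdh over all alternatives was 0.00144 to 0.0556. Of 12 alternative-activation genes, 3 rose and 1 fell, or 4 and 1 adjusted over the list alone. Fn1, Msr1 and Il4ra rose 12.8-fold, 4.09-fold and 2.02-fold, and Tgm2 fell 1.65-fold, while Mrc1 and Arg1 did not pass, at -0.03 and 1.22. Without WT replicate 2, 2 members were called lower, and 3 without it and Cop1 KO replicate 2 together. That list's camera adjusted p = 0.0374 became 0.282 without WT replicate 2 and 0.0526 without Cop1 KO replicate 2, and the adjusted p = 0.283 with an estimated correlation. The call was also lost with no filter (0.0609), at least 1 CPM in 4 libraries (0.154), quality weights (0.0973), the deposited RPKM (0.0574), and without WT replicate 2 and Cop1 KO replicate 2 together (0.345).

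Immediate-early and heat-shock genes, which tissue dissociation induces, were lower in 4 of 25 cases and higher in 1, with the same counts adjusted over the list alone. Socs3 and Jund fell 2.48-fold and 2.22-fold, Ier5 and Atf3 fell by 0.74 and 0.73 on the log2 scale, and Hsph1 rose 1.52-fold. The list was not called (camera adjusted p = 0.0960). WT replicate 2 had the highest level of this list, a median log2 CPM of 6.35 against 4.43, 5.02 and 4.99 in the other WT libraries and 4.32 to 5.57 in Cop1 KO. Without it the list median moved from -0.53 to -0.12, the 4 members called lower were Jun, Jund, Nr4a1 and Socs3, and Ier2 was called higher, at 1.15 (edgeR adjusted p = 0.0026). The list passed without WT replicate 1 (camera adjusted p = 0.0250) and without WT replicate 3 (0.0381), and with no filter on low counts (0.0188). The number of lower members was 2 without WT replicates 1 or 4 and without Cop1 KO replicates 1, 3 or 4, and 5 without WT replicate 3. Without WT replicate 2 and Cop1 KO replicate 2 together, 7 were lower and 2 higher, with a median of -0.03. The calls of Atf3 and Hsph1 ended without any 1 of those 5 libraries or WT replicate 2, and that of Ier5 without WT replicate 2 (edgeR adjusted p = 0.0759).

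None of 16 neuron markers was called in the edgeR test at either adjustment, and the list median was 0.69 (camera adjusted p = 0.211). Cop1 KO replicate 2 had a median neuron marker level of 3.01 log2 CPM, where the other Cop1 KO libraries had 0.62 to 1.32 and the WT libraries 0.30 to 1.52. Without it the median was -0.22. The astrocyte list held 1 lower gene of 14, Slc1a3, also adjusted over the list alone (median 0.94; camera adjusted p = 0.274), and the oligodendrocyte list none of 12 at either adjustment (median 0.53; camera adjusted p = 0.0990). Without Cop1 KO replicate 2 these medians were 0.09 and 0.19. The Slc1a3 call ended without WT replicate 3 or Cop1 KO replicates 1 or 3. The neuron and oligodendrocyte lists passed as sets without Cop1 KO replicate 1 (camera adjusted p = 0.0455 and 0.0210). Without Cop1 KO replicate 3 the neuron, astrocyte and oligodendrocyte lists passed, each at an adjusted p of 0.0495. Of 12 endothelial and mural cell markers, Flt1 rose 9.63-fold and Pecam1 fell 3.96-fold, also adjusted over the list alone. That list's median of 0.52 and the downward direction of its camera test (adjusted p = 0.940) differ in sign, and the median was -0.66 without Cop1 KO replicate 2.

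Of 14 border-associated macrophage markers, Siglec1 rose and no other passed at either adjustment, with a median of 0.00 (camera adjusted p = 0.485). WT replicate 2 held the lowest level of this list, 1.28 log2 CPM, where the other WT libraries had 3.67 to 4.44 and the Cop1 KO libraries 3.19 to 4.02. Without it 3 members were called lower in Cop1 KO. Of 16 monocyte markers, 3 rose, among them Fn1 and Ms4a4c, and none fell, also adjusted over the list alone. The list's median of -0.06 and its mean of 0.43 differ in sign, and Ccr2, the receptor typical of inflammatory monocytes, stood at 0.03 (SE 0.60). The upward camera test (adjusted p = 0.0245) became 0.788 without WT replicate 2 and 0.0663 without Cop1 KO replicate 3, and the adjusted p = 0.585 with an estimated correlation. It became 0.110 with quality weights, 0.0995 with the deposited RPKM, 0.178 with fry, and 0.521 without WT replicate 2 and Cop1 KO replicate 2 together. Of 11 lymphocyte markers, Ccl5 rose 8.08-fold and Cd79b fell 1.81-fold, also adjusted over the list alone (camera adjusted p = 0.477). Of 16 listed neutrophil markers only 4 had enough reads to be tested. Of these, Cxcr2, Csf3r and Lcn2 rose, also adjusted over the list alone, Csf3r from 534 ± 36.1 to 1091 ± 210 CPM (SD, n = 4). Cxcr2 and Lcn2, with 10 and 2 reads in WT, passed the filter through Cop1 KO and could be called only as higher. The set test of this list is therefore no measure of neutrophil content. Against the other tested genes, the camera adjusted p = 0.000545, and the adjusted p = 0.221 with an estimated correlation. Among red blood cell markers 1 was measured, Car2, which did not pass (1.14, SE 0.52; edgeR adjusted p = 0.169).

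**Figure D3:**
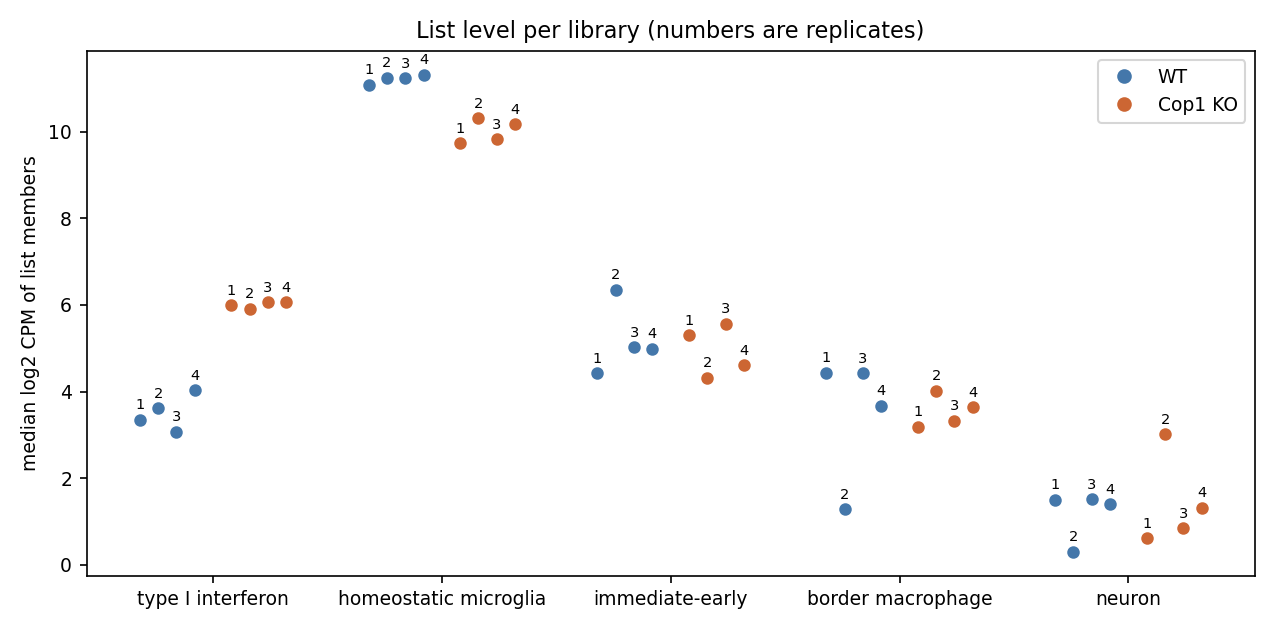
Median log2 CPM of the members of 5 gene lists in each library, with WT in blue, Cop1 KO in orange and replicate numbers above the points. The groups separated for the interferon and homeostatic lists. WT replicate 2 was highest for immediate-early genes (6.35) and lowest for border macrophage markers (1.28), and Cop1 KO replicate 2 was highest for neuron markers (3.01).

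Mitochondrially encoded transcripts, a sign of RNA and cell quality, were higher in Cop1 KO for 6 of 7 measured genes, or 7 of 7 adjusted over the list alone, with a median log2 change of 0.83. They held 0.14% to 0.27% of the reads in Cop1 KO libraries and 0.09% to 0.14% in WT. The number called was 4 without WT replicates 1, 2 or 3 or Cop1 KO replicate 1, and 4 without WT replicate 2 and Cop1 KO replicate 2 together, with a median of 0.59. ND1 rose 1.59-fold, and ND2, ND4 and ND6 1.78-fold, 1.88-fold and 1.84-fold. For the list as a set, the camera adjusted p = 0.000332, and the adjusted p = 0.283 with an estimated correlation. Xist was the single sex-linked gene tested, at 0.68 (SE 0.24; edgeR adjusted p = 0.0841). It passed without WT replicate 2, at 0.86 (adjusted p = 0.0351), and without Cop1 KO replicate 3, at 0.81 (adjusted p = 0.0492), as well as in the DESeq2 Wald test (0.0284) and with quality weights (0.0343), and the range for Xist over all alternatives was 0.0284 to 0.219. The 4 Y-linked genes had 0 reads in each library.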

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

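The tests on monocyte, border macrophage and lymphocyte markers, on interferon genes off chromosome 1, on chromosome windows, on neutrophil reads, on Jund, Socs3, Atf3 and Ier5 without one library, and the splits counted with fry were chosen only after the result was seen.

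Of 226 sets of 4 libraries examined for 113 named genes, 13 had one library far from the other 3, where chance gives about 1 in 20; the gap to the nearest library is given as a share of the group's range on log2 CPM. WT replicate 3 was low for Tmem44 (0.969) and high for Mycl (0.834), Cebpb (0.881), Phgdh (0.868) and Slc1a3 (0.888). WT replicate 2 was low for Apoe (0.905), Snap25 (0.875) and Car2 (0.910). Cop1 KO replicate 3 was high for H2-K1 (0.891) and Dnajb9 (0.836) and low for Srebf2 (0.831). Cop1 KO replicate 4 was high for Il1rn (0.930), and Cop1 KO replicate 2 was low for Psat1 (0.871).

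Interferon response genes were higher in all 4 Cop1 KO libraries, and more leukocytes of other types in those preparations would be a technical source. Monocyte, border macrophage and lymphocyte markers had median log2 changes of -0.06 (95% bootstrap interval over genes -0.34 to 1.16), 0 (-0.57 to 0.22) and 0.16 (-0.26 to 0.62). Each interval lay below 1.26, which is 0.5 times the list's median. This argues against border macrophages and lymphocytes as the main source. For monocytes the upper bound of 1.16 is close to that limit, so the test does not decide. The intervals treat genes as independent, while the estimated correlation was 0.59 for monocyte and 0.69 for border macrophage markers, so they may be too narrow. They also leave out the spread between libraries. Since 3 monocyte markers rose, a contribution of such cells is not excluded. DNA that came along with the altered Cop1 allele and acts on its own neighbours was argued against too, since the 32 list members on other chromosomes were all called, with a median of 2.52. Neighbouring DNA does stay open for 11 genes of the Ifi200 family (chromosome 1, 173349547 to 174031755, about 14 Mb from Cop1), of which 7 rose while Aim2, Mndal, Ifi203 and Ifi208 did not pass: among other genes within 20 Mb of Cop1, 54 of 199 (27.1%) were called against 15.6% elsewhere (odds ratio 2.02, 1.44 to 2.78), and 0% of 12810 overlapping windows of that size elsewhere had as high a share, the highest being 24.2%, although within 5 Mb the odds ratio was 1.17 (0.50 to 2.46). The excess was uneven. In steps of 5 Mb, 25 of 66 other genes (37.9%) were called at 10 to 15 Mb beyond Cop1, the step that holds the family. The steps on either side of Cop1 had 15.4% and 20.8%. An effect of Cop1 loss on interferon signalling is thus a hypothesis for the genes off chromosome 1, and an indirect effect of a linked variant on them was not tested, since the labels name no strain.

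Cxcr2 rose from 10 reads in WT to 6106 in Cop1 KO, and neutrophils would bring it. S100a8 and S100a9, among the most abundant transcripts of neutrophils, together had 48 reads in Cop1 KO, 0.79% of the Cxcr2 reads, all of them in replicate 2, and 0 in the other 3 libraries, which argues against neutrophils as the source. Replicate 2 also held 124 Ngp and 74 Ltf reads, so a trace of neutrophil RNA may be present there. Whether the region around Cxcr2, 85.1 Mb from Cop1, differs as a whole cannot be told apart from an effect of genotype, because the odds ratio for calls within 5 Mb was 1.14 with a wide interval (0.51 to 2.29). A response of microglia to Cop1 loss stays open as a hypothesis.

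Of 25 immediate-early and heat-shock genes, 4 were lower and 1 higher in Cop1 KO and the list was not called, and WT replicate 2, with the highest level, may account for much of its median of -0.53. Without that library the list median moved to -0.12, Jun and Nr4a1 became called as lower and Ier2 as higher (1.15), so for the list as a whole the library and the genotype cannot be told apart. Jund and Socs3 stayed past the threshold, at -0.84 and -1.03, which argues against that library as their whole cause. Atf3 and Ier5 moved to -0.62 and -0.43 and missed the threshold. Atf3 measured 31.6 CPM in WT replicate 4 and 31.4 in WT replicate 2, so replicate 2 did not stand apart for that gene. Whether the falls of Atf3 and Ier5 hold without it stays open with 3 WT libraries left. An effect of genotype was not separated from handling time, which the labels do not give.

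Among the 35 splits of the 8 libraries into 4 and 4, no other split called as many genes as the 2398 of the real one. This is 1 split in 35, the smallest share possible, so chance is made unlikely but is not excluded. The highest other split called 0 genes in the edgeR test, and at most 2017 at an unadjusted p under 0.05 against 4466 in the real one. Each other split mixes WT and Cop1 KO libraries, which adds the difference between the groups to the spread and lowers the number of calls. For lists called by camera with its preset correlation, 5 of the 35 splits gave at least the real 18, the highest other giving 22, so chance cannot be excluded for that number. With fry the real split called 19 lists and the highest other 1 (1 split in 35 as many). The same limits hold for that number, so it does not exclude chance either.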

How the results depend on the processing

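The alternative that leaves out WT replicate 2 and Cop1 KO replicate 2 together was chosen after seeing the data. The number of changed genes lay between 1782 and 3143 under the other scalings, filters and tests and with libraries left out, against 2398; 72.1% to 100% of the 2398 were called again, none with the other sign. A required change of more than 1.5-fold (glmTreat) left 707 changed genes, 436 higher and 271 lower, as a stricter null must. Under the other scalings the share of higher genes among calls lay between 49.5% with upper-quartile scaling and 56.7% with library size only, against 53.5%. It was 56.9% without Cop1 KO replicate 1 and 61.7% with glmTreat. Scaling moved the median of all genes by under 0.1. Cop1 stayed below WT and short of the threshold in each alternative that gave a value, at an adjusted p of 0.0699 to 0.271. Of 2015 comparisons of a named gene with its value under an alternative, 41 lost and 19 gained a call and 0 reversed. Of 539 such comparisons for lists, 40 lost and 16 gained a call. The median of the border macrophage list, 0.00 and not called, was -0.719 with a downward call (adjusted p = 0.0352) without WT replicate 2 and Cop1 KO replicate 2; WT replicate 2 had the lowest level of those markers. Camera with an estimated correlation called 0 lists against 18 with the preset one and 19 with fry, and 4 lists had an unadjusted p under 0.05. A higher correlation widens the null of camera, but it was not the only difference between these settings. The lipid efflux and storage list had an estimate of -0.021, below the preset 0.01. Its camera adjusted p still went from 0.0890 to 0.221, though adjusted values also depend on the other lists. The acute-phase and sterol lists, with low estimates of 0.038 and 0.052, lost their calls too. How much of the drop is due to the correlation was not separated. Depth and number of libraries limit small changes, of which simulated data recovered 16.4% at 1.5-fold.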

Other observations

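The family tests were chosen after the data were examined. Tested genes were grouped by the stem of their symbol, and each family with at least 5 members was tested for an excess of calls with Fisher's exact test, adjusted over families and directions. That test treats members of a family as independent. Related genes can move together, so its p-values may be too small and serve only to rank families. The Tnfsf stem, ligands of the tumour necrosis factor superfamily, had 6 of 7 members higher in Cop1 KO and none lower (adjusted p = 0.000901). Superfamily ligands with other symbols, such as Tnf, were not counted in it. Tnfsf8, the ligand of CD30, rose by 3.82 on the log2 scale, from a mean of 2.20 to 31.0 CPM. Tnfsf13, which encodes APRIL, and Tnfsf10, which encodes TRAIL, rose by 1.72 and 0.89, and Tnfsf9 did not pass, at 0.18. The counts of this family were the same under each of the 4 scalings.

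The Ifi stem had the smallest p, with 12 of 15 members higher and 1 lower (Fisher's exact test adjusted p = 3.79e-08). Of the 12, 7 are the risen Ifi200 family genes on chromosome 1, for which DNA around Cop1 stays open. The lower member was Ifi27, at -0.99. Guanylate-binding proteins, GTPases induced by interferon, rose in 6 of 8 cases (adjusted p = 0.00146), with Gbp2 at 1.86 and Gbp4 at 2.15, while Gbp7 did not pass, at 0.07. With upper-quartile scaling 5 of them were called. Schlafen genes rose in 5 of 7 cases (adjusted p = 0.00727), with Slfn2, Slfn1 and Slfn9 at 1.65, 2.05 and 1.51 outside the interferon list. Cxcl chemokines rose in 6 of 9 cases (adjusted p = 0.00255). Large-subunit ribosomal protein genes rose in 14 of 46 cases with none lower (adjusted p = 0.00224), with Rpl32 and Rpl4 at 1.12 and 0.76. Mitochondrially encoded ND genes, a sign of RNA and cell quality, rose in 5 of 5 cases in the same libraries, with a median of 0.83 against 0.69 for the ribosomal genes. The ribosomal counts rest on the uniquely aligned part of their reads, and with the other scalings 13 to 15 rose. In the other direction, 4 of 7 Gimap genes, GTPases named for immunity, were lower, an excess that missed the threshold (adjusted p = 0.0674).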
